A study of Arabidopsis thaliana with 12 samples.

How the data were processed

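Total RNA of Arabidopsis thaliana shoots and roots was hybridised to 12 ATH1 arrays, 3 for each combination of tissue (shoot, root) and exposure (control, cs). Group and replicate number were taken from the sample titles and the tissue from the sample characteristics. The values analysed are the deposited MAS5 intensities, 1 value per probe set and array on a linear scale, and MAS5 is named in the submitters' processing notes without a version. Per array, the 2% trimmed mean of the deposited intensities was 100, which is the mark of MAS5 scaling. Background correction and detection calls are not given in the sources used here, and no further normalization between arrays was applied in the main analysis. No pair of arrays held identical values (0 pairs).

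The table holds 22810 probe sets, of which 64 are Affymetrix controls. In the platform annotation, 13513 of the other 22746 probe sets name 1 gene, 503 name several and 8730 are not listed there and are unnamed here. Symbols were updated through the TAIR10.1 RefSeq gene table, in which 13436 of the 13513 were found. No coordinates are given, since the array's genome build is not given in the sources used here. Probe sets with several genes or none entered the tests and the counts but are not named.

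Intensities were transformed as log2(signal + 11), the pseudocount being 0.25 times the median of the array medians, rounded to a whole number. Fold changes on this scale understate the change of dim probe sets. Probe sets were tested if their mean log2 signal in at least 1 tissue reached the 40th percentile of that tissue (a signal of about 28.0 in shoot and 31.2 in root), which left 15508, of which 8458 name 1 gene. Limma 3.58.1 in R 4.3.3 was fitted to all 12 arrays with a mean for each of the 4 groups (8 residual degrees of freedom), with lmFit and eBayes with an intensity trend, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The contrasts were Cs against control in shoot, Cs against control in root, their difference, and root against shoot of control plants. The choices in this paragraph, the fixed gene lists, the naming rule and the alternatives to be run, apart from those named below as added, were set before the data were examined.

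In all, 14 gene lists with 312 genes were fixed from general knowledge, and 42 of these genes have a probe set of their own, 33 of them tested. The lists with at least 3 tested probe sets (5 lists: antioxidant enzymes, cell cycle, flavonoid synthesis, photosynthesis, reactive oxygen-responsive genes) were tested with limma's camera with a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry. Because the annotation used here is thin, 20 further gene groups were defined after it was seen and before any contrast was computed. Most were defined from gene names in the annotation, and the plastid-encoded genes by their chromosome. The class III peroxidases and the cytosolic ribosomal proteins were lists of loci written out by hand. The peroxidase list leaves out AT2G41480, so it is not the whole family. Of the 20 groups, 19 had at least 3 tested probe sets, and their camera p-values were adjusted as a family of their own.

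For each Cs contrast the named genes are the 12 largest rises and the 12 largest falls past the threshold among probe sets whose 3 Cs arrays all lie on one side of the 3 control arrays, filled to 6 in each direction by the smallest unadjusted p. For the difference between tissues the rule took 6 in each direction filled to 4, and for root against shoot 6 in each direction. In each fixed list every member past the threshold was named up to 4, filled to 2 by the smallest p. The rule also held 7 genes to be named in any case, for which 0 probe sets name the gene alone, and they are not analysed here. Other genes named in the text are members of the lists or were chosen after their values were seen.

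Replicate numbers are shared between groups, so it was checked whether same-numbered arrays deviate together from their group means. In shoots the correlation of these deviations over probe sets was 0.71, 0.41 and 0.45 for numbers 1, 2 and 3. Between control and Cs shoots of numbers 2 and 3 it was 0.2 and 0.37, not far below. The numbers thus pair the shoot samples mainly by setting number 1 apart, on the data and not on a statement in the labels. Fits with a replicate block were run as alternatives. Other alternatives were the pseudocount, the filter, quantile normalization, array-median centring, no intensity trend, array weights, the arrays of 1 tissue alone, and leaving out each array in turn. Leaving out the 4 arrays numbered 1, and following the photosynthesis and plastid-encoded medians in root and in the difference between tissues through the alternatives, and the block in the tests of the added gene groups, were added after seeing the data.

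The limma and camera steps were tested on simulated data with the real means and spreads of 15508 probe sets and 200 changed genes per run, in 10 runs for each tissue. Noise was drawn independently for each probe set, without differences by replicate number or correlation between genes. Changes were added on the log2(signal + 11) scale, so a given fold is a larger change in signal for dim probe sets. For shoots, 11.4%, 56.8%, 83.8% and 93.2% of genes changed 1.5-, 2-, 3- and 4-fold were recovered, and 5.33% of all calls were false. For roots the shares were 12.8%, 57.6%, 86.4% and 91.8%, with 4.97% false calls. A shift of 0.6 (log2) in all members of the photosynthesis list was found by camera in 6 of 10 shoot runs and 8 of 10 root runs.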

Results

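Transcript levels were measured on 12 Affymetrix ATH1 arrays of Arabidopsis thaliana, a small flowering plant used as a laboratory model, in a series on low chronic exposure to caesium-137, a radioactive isotope that emits beta and gamma radiation. Shoots and roots came from control plants and from plants labelled cs, taken here as the caesium-exposed (Cs) plants from the series title, with 3 arrays in each of the 4 groups. The labels give the developmental stage as 1.0 for every array and state neither the dose nor the length of exposure. Nothing in them says that the replicates came from separate plants or cultures, so p-values measure only the spread between these samples, which may be technical. The median signal of the arrays lay between 41.1 and 49.6, and the number of arrays limits the precision. Across the tested probe sets, log2 signals correlated between 0.927 and 0.975 within a group, between 0.922 and 0.981 between control and Cs arrays of the same tissue, and between 0.418 and 0.583 between tissues. Group values below are mean signal ± SD over 3 arrays, and fold changes are log2 values on the log2(signal + 11) scale with their standard error (SE). The fit shares a single spread per probe set over the 4 groups, so the SE is the same in shoot and root. Noise in one tissue therefore enters the SE and p-value of the other. PSAE-1 had 4320 ± 210 in control and 4224 ± 117 in Cs shoots, yet a shoot log2 fold change of -0.03 ± 0.53.

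The first comparison asked which transcripts differed between Cs and control shoots. No probe set passed the adjusted threshold in shoots. MT1C, a metallothionein gene whose product binds metal ions, had a signal of 885 ± 70.2 in control and 1322 ± 130 in Cs shoots, a log2 fold change of 0.57 ± 0.13. AT3G09700 had the smallest p of the higher group by the naming rule, with 34.8 ± 7.92 in control and 70.1 ± 14.5 in Cs shoots (log2 fold change 0.82 ± 0.175, limma, adjusted p = 1). On the lower side, AT3G56410 had 21.1 ± 4.20 in control and 5.03 ± 2.35 in Cs shoots (log2 fold change -1.005 ± 0.23, and -1.64 or -0.41 with a pseudocount of 2.75 or 44). All of these lay apart from the controls in 3 of 3 Cs arrays, which the naming rule requires, and none passed the correction.

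The other 4 genes named on the higher side, AT2G46850, AT4G18340, AT2G43250 and AT5G54020, had log2 fold changes of 0.75, 0.79, 0.93 and 0.69, and of 0.34, 0.34, 0.40 and 0.26 with a pseudocount of 44, as they are dim in shoots. AT4G18340 went from 9.64 ± 5.86 to 24.0 ± 5.98 in shoots and stood at 147 ± 7.29 in control roots. All 6 named genes on the higher side had higher signals in control roots than in control shoots, with log2 differences from 1.02 for AT3G09700 to 2.97 for AT4G18340 that passed the limma test. Genes picked for a low control shoot signal are favoured in that comparison. AT2G46850, AT4G18340, AT2G43250 and AT5G54020 also lay under the shoot filter level of 28.0 in both control and Cs shoots. They were tested only through their root signal, so for them a root excess was a condition of being tested. Among Cs plants AT3G09700 was lower in root (58.4 ± 5.97) than in shoot, the other 5 being higher. Root-enriched transcripts as a set lay on the same side, since the 108 probe sets at least 16-fold higher in control roots had a median shoot log2 fold change of 0.37 and 90 of them were above 0. Chosen in Cs plants, 93 such probe sets had a median of 0.30 with 74 above 0. The other 5 genes named on the lower side were AT1G29195, AT4G09160, AT4G25660, CXE16 and AT2G44420, with log2 fold changes of -0.85, -0.65, -0.54, -0.91 and -0.97. With a pseudocount of 2.75 or 44, AT1G29195 had -1.37 or -0.35 and AT2G44420 -1.53 or -0.42, and with 44 AT4G09160 had -0.35 and CXE16 -0.51. AT4G25660 was the most abundant of them, with 137 ± 15.6 in control and 90.3 ± 5.75 in Cs shoots.

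Among the gene lists fixed for DNA damage, DNA repair, oxidative stress, ion transport and metabolism, none of the tested members passed in shoots, over all probe sets or adjusted over the list alone. AT4G22960, the only tested member of the DNA damage-induced transcripts, had a log2 fold change of -0.04 ± 0.195, and of the DNA repair genes UNG, a uracil DNA glycosylase, had -0.11 and ATLIG4, a DNA ligase, -0.03. In the antioxidant enzymes 0 of 5 members passed. GR, a glutathione reductase, had 817 ± 156 in control and 672 ± 119 in Cs shoots, and AT3G11630 had a log2 fold change of 0.09 ± 0.18. In the reactive oxygen-responsive genes 0 of 6 passed, with 0.25 ± 0.38 for STZ, a zinc finger factor, and -0.15 ± 0.18 for WRKY6. DFR and UF3GT, enzymes of anthocyanin synthesis, had log2 fold changes of -0.76 ± 0.53 and -0.62 ± 0.57, and the 3 tested flavonoid genes gave a camera adjusted p of 0.415 (0.972 with an estimated correlation). The flavonoid list passed as lower without control shoot replicate 2 (adjusted p = 0.00577) or Cs shoot replicate 1 (0.0129). It turned to higher without control shoot replicate 1 (0.761) and gave 0.815 without Cs shoot replicate 2. All 3 genes were higher in the shoot arrays numbered 1, by a median log2 difference of 1.53. Leaving out 1 array therefore also unbalances the numbers. With the replicate block over the arrays of both tissues the list stayed on the lower side and did not pass (camera adjusted p = 0.084, and 0.848 with an estimated correlation). The photosynthesis list (6 members) had a median of -0.12, the cell cycle list (5 members) 0.00, the antioxidant list -0.07 and the reactive oxygen list 0.12, and none of these lists passed. AT1G60160, the only gene of the potassium and caesium transport list with a probe set that names it alone, had -0.02 ± 0.32. GI, a clock gene, had -0.23 ± 0.60 and GRX480, a glutaredoxin of the salicylic acid response, 0.45 ± 0.27. Only 4 of 18 genes of the heat shock list and 1 of 22 of the touch list had a probe set that names the gene alone. None of these probe sets was bright enough to be tested. PYK10 and EXPA7, genes typical of roots, had 0.09 ± 0.28 and 0.23 ± 0.34.

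By limma with Benjamini-Hochberg adjustment, 0 of 15508 probe sets passed in shoots, and 324 had an unadjusted p under 0.05, 239 of them higher and 85 lower in Cs shoots, where an even spread of p-values would give 775.4. With the replicate block in shoot arrays alone 0 passed and 934 had an unadjusted p under 0.05, above the even spread. With the block over the arrays of both tissues 516 had an unadjusted p under 0.05, still below the even spread. The block raised the count in each case. The block over both tissues takes the same number effect for shoots and roots. Same-numbered arrays of different tissues deviated together only weakly (correlations 0.04 to 0.28). The count of 516 therefore cannot tell whether the shortfall outlasts pairing within shoots. The 3 Cs arrays lay on one side of all 3 control arrays in 6.35% of probe sets, where chance gives 10% for arrays without pairs. The median 95% confidence half-width of a log2 fold change was 0.43, or 1.35-fold. In simulated shoot data 56.8% of genes changed 2-fold and 93.2% of genes changed 4-fold were recovered. The simulated noise held no differences by replicate number, so these shares may not carry over to the real arrays.

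**Figure D1:**
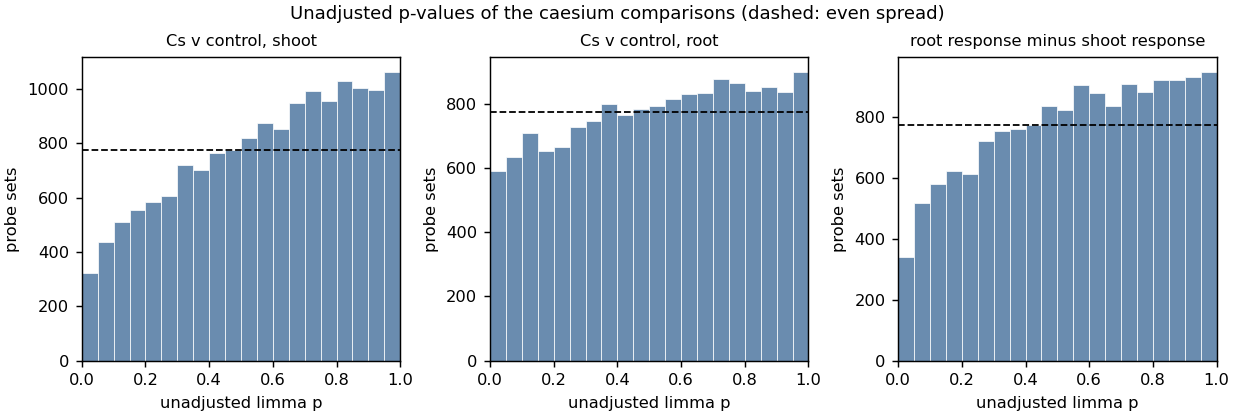
Unadjusted limma p-values of all 15508 probe sets in the fit without a replicate block, in 20 bins (x axis, p; y axis, number of probe sets; dashed line, 775.4 per bin under an even spread) for Cs against control in shoot, in root, and for the difference between them. The lowest bin holds 324, 589 and 341 probe sets, each under the dashed line.

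The second comparison asked which transcripts differed between Cs and control roots. No probe set passed the adjusted threshold in roots in the fit to all 12 arrays with the pseudocount of 11. AT4G08380, which encodes a proline-rich extensin-like protein of the cell wall, had the smallest p, with 102 ± 37.1 in control and 336 ± 69.4 in Cs roots (log2 fold change 1.64 ± 0.26, limma, adjusted p = 0.423). It was higher in 3 of 3 Cs roots, which the naming rule requires, and it passed with a pseudocount of 44 (adjusted p = 0.0340). AT2G41480, which encodes the class III peroxidase PRX25, had 150 ± 7.76 in control and 236 ± 11.9 in Cs roots (log2 fold change 0.62 ± 0.125), and did not pass.

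AT1G64590 had 154 ± 42.5 in control and 338 ± 100 in Cs roots, a log2 fold change of 1.08 ± 0.24. AT3G50590 and AT5G55970 had log2 fold changes of 0.85 ± 0.17 and 0.90 ± 0.21. AT2G10940 had 4.92 ± 0.37 in control roots, 43.2 ± 34.0 in Cs roots and 2010 ± 330 in control shoots. Its log2 fold change in root was 1.59 ± 0.33, 1.11 without Cs root replicate 2, and 2.33 or 0.77 with a pseudocount of 2.75 or 44. On the lower side, AT2G34750 was the most abundant, with 536 ± 46.6 in control and 355 ± 20.7 in Cs roots (log2 fold change -0.58 ± 0.15). AT5G55580, which encodes the mitochondrial transcription termination factor family protein mTERF9, had -0.84 ± 0.21, AT1G62030 -0.73 ± 0.18, AT3G09080 -0.75 ± 0.20, the pseudogene AT4G19790 -0.97 ± 0.28 and AT2G20790 -0.58 ± 0.17. With a pseudocount of 2.75 or 44, AT5G55580 had -1.48 or -0.32 and AT1G62030 -1.21 or -0.29, and with 44 AT3G09080 had -0.36, AT4G19790 -0.48 and AT3G50590 0.49. None of these 12 genes passed the correction with the pseudocount of 11.

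The 6 photosynthesis genes with a tested probe set all had higher mean signals in Cs roots, and the list passed camera with the preset correlation, with a median log2 fold change of 0.61 (adjusted p = 0.00867). With an estimated correlation the adjusted p was 0.667. No member passed alone: RCA, the activase of Rubisco, had 151 ± 128 in control and 256 ± 224 in Cs roots, and PSAE-1, a photosystem I subunit, had 78.6 ± 42.9 and 208 ± 227. PRK, the Calvin cycle kinase phosphoribulokinase, had a log2 fold change of 0.71 ± 0.345, LHCB4.1 0.62 ± 0.47, PSBW 0.56 ± 0.50 and PSBY 0.34 ± 0.36. The median signal of the 6 probe sets was 487 in Cs root replicate 2 and lay between 62.6 and 177 in the other 5 root arrays. Other shoot transcripts shared this offset: of the 296 probe sets at least 16-fold higher in control shoots, 255 were above 0 in Cs against control roots (median 0.29), as were 201 of the 249 chosen in Cs plants (median 0.25). The median signal of the 296 was 5.30% of the shoot mean in Cs root replicate 2 and 1.93% to 2.87% in the other roots. Without that array the list median was -0.065 (adjusted p = 0.969). Leaving out control root replicate 2 (median 0.29, adjusted p = 0.205) or control root replicate 3 (0.50, adjusted p = 0.171) also ended the call.

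**Figure D2:**
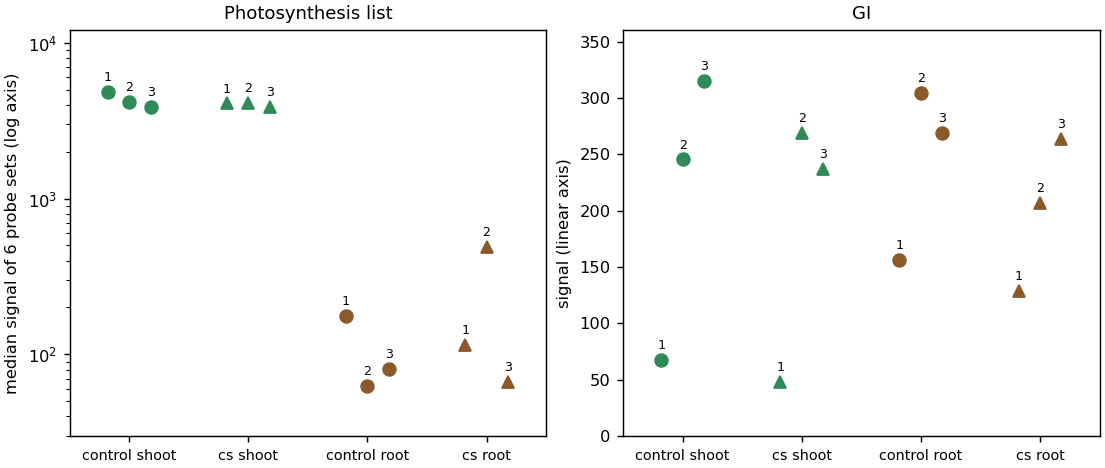
Left, median signal of the 6 photosynthesis probe sets (log axis), and right, signal of GI (linear axis), for each array by group, with the replicate number beside each point. Cs root replicate 2 stands at 487 on the left, above the other 5 roots, and the arrays numbered 1 have the lowest GI signal of each group.

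Of the other fixed lists, none of the members passed in roots over all probe sets. Adjusted over the list alone, only AT4G22960 was under the threshold, and its list has only this tested member. Its list-alone value of 0.0223 is therefore its unadjusted limma p, which was 0.0529 without Cs root replicate 2. AT4G22960 of the DNA damage-induced transcripts had 34.2 ± 10.7 in control and 52.3 ± 4.28 in Cs roots (log2 fold change 0.51 ± 0.195, and 0.31 with a pseudocount of 44; limma, adjusted p = 1 over all probe sets) and was higher in 3 of 3 Cs arrays. The repair genes UNG and ATLIG4 had -0.23 ± 0.26 and 0.07 ± 0.17. AT1G19020 of the reactive oxygen-responsive genes had 118 ± 61.8 in control and 237 ± 125 in Cs roots, and WRKY6 had 93.8 ± 19.1 and 72.6 ± 6.22, lower in 3 of 3 Cs arrays. The antioxidant genes SAPX and GR had log2 fold changes of -0.16 ± 0.19 and -0.13 ± 0.21, and the potassium transporter gene AT1G60160, lower in 3 of 3 Cs arrays, had -0.46 ± 0.32. UGT78D2 and DFR of flavonoid synthesis had -0.34 ± 0.51 and -0.34 ± 0.53. PRL, a replication licensing gene, had 0.20 ± 0.17 and AUR2, a mitotic kinase, 0.14 ± 0.18. The root markers PYK10 and EXPA7 had 0.16 ± 0.28 and 0.11 ± 0.34, GI had -0.27 ± 0.60 and GRX480 0.18 ± 0.27. The medians were -0.00 for the antioxidant list, 0.03 for cell cycle, -0.34 for flavonoid synthesis and 0.11 for the reactive oxygen list, and the smallest camera adjusted p of these 4 lists was 0.556.

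By limma, 0 of 15508 probe sets passed in roots, and 589 had an unadjusted p under 0.05, 391 of them higher and 198 lower in Cs roots, in the fit without a replicate block. In 8.89% of probe sets the 3 Cs arrays lay on one side of all 3 control arrays, where chance gives 10%. Over all alternatives run the count in roots lay between 0 and 11, the 11 arising with the replicate block in root arrays alone. Without Cs root replicate 1 it was 7, and without the 4 arrays numbered 1, an alternative chosen after seeing the data, it was 5. In simulated root data, also without differences by replicate number, 57.6% of genes changed 2-fold and 91.8% of genes changed 4-fold were recovered. These shares may not carry over to the real arrays.

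**Figure D3:**
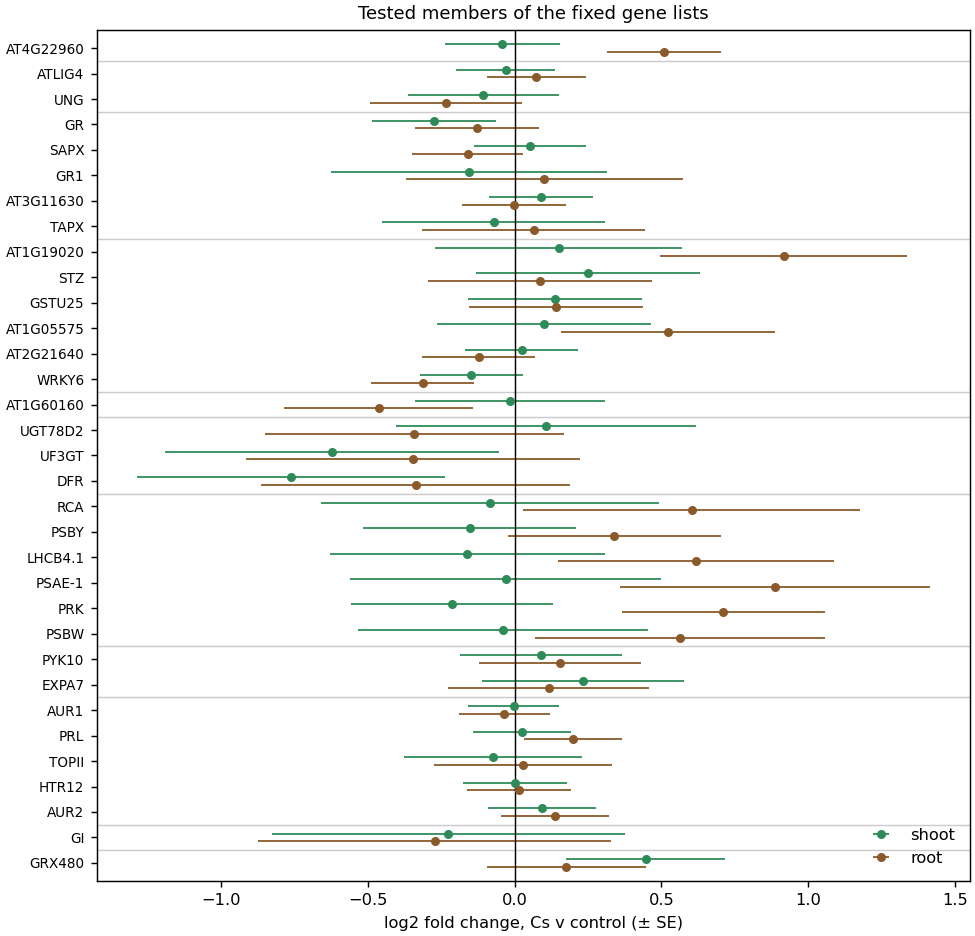
Log2 fold change (x axis, ± SE) in Cs against control shoots (green) and roots (brown) for each tested member of the fixed gene lists (y axis, lists parted by grey lines). The SE comes from a spread shared by both tissues and is not that of the tissue shown. None of the members passed the threshold adjusted over all probe sets, and the 6 photosynthesis genes from RCA to PSBW lie above 0 in root, an offset that rests on Cs root replicate 2.

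The third comparison asked whether the response to Cs differed between roots and shoots. AT3G09700 had the smallest p of the genes named by the rule, with a log2 fold change of 0.82 in shoots and -0.41 in roots and a difference, root minus shoot, of -1.23 ± 0.25 (limma, adjusted p = 1). AT4G08380 had 1.52 ± 0.36, AT2G10940 1.62 ± 0.46, AT4G30490 0.80 ± 0.22 and AT5G38070 0.78 ± 0.22. AT5G40490, AT1G68500 and AT5G46840 had differences of -0.83 ± 0.205, -0.82 ± 0.21 and -0.75 ± 0.22. None of these 8 genes passed. Limma called 0 of 15508 probe sets, with 341 at an unadjusted p under 0.05, and the median 95% confidence half-width of the difference was 0.61. The photosynthesis list differed between tissues in its response by a median of 0.73 with the preset correlation (adjusted p = 0.00827, and 0.952 with an estimated correlation). This difference rests on Cs root replicate 2, without which the median was 0.061 (adjusted p = 0.797).

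Roots and shoots of control plants differed in most transcripts, which checks the tissue labels. Photosynthesis genes were lower in root in 6 of 6 members, with a median log2 difference of -5.45. PRK stood at 3367 ± 500 in shoots and 38.3 ± 28.1 in roots (-6.23 ± 0.345, limma, adjusted p = 1.73e-08). The largest shoot excess of a named gene was that of ECS1, a cell wall protein gene, with 5114 ± 563 in shoots and 14.1 ± 15.1 in roots (-7.83 ± 0.83), followed by AT2G10940 (-6.98 ± 0.33), AT1G09310 (-6.94 ± 0.60), the calmodulin-like gene AT2G41090 (-6.74 ± 0.60), AT1G23130 (-6.57 ± 0.45) and the lectin-like gene AT5G03350 (-6.23 ± 0.68). Root signals of these genes are near the floor, so their differences and order follow the pseudocount: AT1G23130 had -8.07 with 2.75 and -4.78 with 44. Higher in root were AT4G15390 with 19.0 ± 23.8 in shoots and 1432 ± 63.9 in roots (5.87 ± 0.57), AT4G33720 (5.77 ± 0.52), the class III peroxidase gene AT3G01190 (5.73 ± 0.47), AT4G22212 (5.63 ± 0.73), AT2G21045 (5.60 ± 0.54) and AT4G39675 (5.54 ± 0.68). Their shoot signals are low and variable, and with a pseudocount of 44 the order turned, with AT4G22212 at 4.77 ahead of AT4G15390 at 4.61. All 12 passed the limma test.

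The root markers PYK10, a beta-glucosidase of endoplasmic reticulum bodies, and EXPA7, a root hair expansin, were higher in root by 2.85 ± 0.28 and 1.56 ± 0.34. Of the antioxidant enzymes 3 of 5 were lower in root, among them TAPX, the thylakoid ascorbate peroxidase, by -3.92 ± 0.38, and GR by -2.16 ± 0.21. Of the reactive oxygen-responsive genes 5 of 6 were higher in root, with 1.67 ± 0.18 for WRKY6 and 1.75 ± 0.42 for AT1G19020, and AT2G21640 was lower by -0.95 ± 0.19. In the cell cycle list 1 of 5 members, AUR1, was higher in root (0.38 ± 0.155, limma, adjusted p = 0.0498), and 0 of 5 passed adjusted over the list alone. The 3 flavonoid genes did not pass. By camera the photosynthesis list was lower in root (adjusted p = 3.88e-05, and 0.292 with an estimated correlation), while the antioxidant list (0.0514) and the reactive oxygen list (0.279) did not pass. In limma's test 9350 of 15508 probe sets passed, 5890 higher and 3460 lower in root. The median log2 difference over all probe sets was 0.24, and 0.14 after centring each array on its median, so differences of single genes stand on that offset. In Cs plants 9000 probe sets passed the same comparison. Of these, 8087 also passed in control plants, 8085 of them in the same direction.

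The 3' to 5' signal ratio of the control transcripts, a sign of RNA quality, was compared between Cs and control arrays. The mean log2 ratio was taken over 6 pairs of control probe sets, which cover only 3 transcripts (Actin, GAPDH and Ubq, 2 pairs each). In shoots it was 1.15 ± 0.33 in control and 1.08 ± 0.12 in Cs arrays (exact permutation test, two-sided p = 0.8). In roots it was 1.18 ± 0.20 and 0.96 ± 0.15 (exact permutation test, two-sided p = 0.2). The root ratio was lower in Cs for all 6 pairs, and the mean was lower at each replicate number. The smallest p that 3 against 3 arrays allow is 0.1. By replicate number, the mean ratio in shoots was 0.88 for number 1, 1.14 for number 2 and 1.32 for number 3. Shoot arrays with the same number resembled each other, and 2536 probe sets differed by number in shoots and 244 in roots (limma, adjusted).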

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

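Of the tests in this part, those on Cs root replicate 2, on the level in each Cs root, on the RNA quality ratios and the splits for the Cs comparisons were chosen after the result was seen. The matched random lists replaced a first form of the shoot RNA test after its outcome was seen. The tests of array scaling and of GI were set before their values were seen.

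The photosynthesis list stood out because its response to Cs differed between root and shoot, with a median difference of 0.73 (log2), and the plastid-encoded genes, a group of 68 probe sets, did so with a median difference of 0.19 (camera adjusted p = 0.0162, and 0.972 with an estimated correlation). In roots the plastid-encoded genes had a median log2 fold change of 0.25 (adjusted p = 0.000128, and 0.823 with an estimated correlation). Without Cs root replicate 2 they turned to -0.16 in roots (adjusted p = 0.0119) and to -0.25 in the difference (adjusted p = 0.028). Without Cs root replicate 2 the photosynthesis median in root went from 0.61 to -0.065, so this single library carries the shift. A rise with exposure in all Cs roots is argued against, as 1 of 3 Cs roots lay above all control roots, and so is array scaling, as quantile normalization left the median at 0.66. A share of shoot RNA in that library may account for the photosynthesis list: its median excess was 7.21% of the shoot signal, inside the range of 3.54% to 7.55% that held 95% of 10000 random lists of shoot-enriched probe sets matched on signal, though near its upper end. For the plastid-encoded genes the excess was 11.3%, outside 2.51% to 3.66%. The random lists came from probe sets at least 16-fold higher in control shoots and were matched on shoot signal alone. Plastid-encoded genes were lower in root by a median log2 difference of only -3.25. Their median signal varied from 56.0 to 109 in the other roots, which also enters the excess. For these genes the test cannot decide on an even share of shoot RNA, and green root tissue, which was not tested, stays open.

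Shoot arrays numbered 1 stood apart from numbers 2 and 3, with first principal component scores of 42.5 and 37.5 against -13.8 to -24.7. No biological explanation in the design was tested, since the labels do not say what a number marks. Array scaling is argued against, since 2381 probe sets still differed by number after quantile normalization, against 2536 without it. A different time of day at harvest is a candidate explanation: GI was lower in number 1 by -2.01 (log2; limma, adjusted p = 4.1e-06). GI was the only clock gene of the fixed list with a probe set that names it alone. The idea came from CCL (-3.40), already seen among the genes with the smallest p. In shoots RNA quality cannot be told apart from it, since the lowest mean log2 3' to 5' ratio of the other 4 shoot arrays lay 0.205 above the highest of number 1. In roots number 1 also had the lowest mean ratio (0.927 against 1.24 and 1.04). The lowest single array, Cs root replicate 3 (0.852), had a component score of -32.9, opposite to number 1 (34.4 and 20.2), which goes against RNA quality. The mean and this 1 array point different ways, and RNA quality stays open there too.

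For the shoot and root comparisons, 3 arrays against 3 make 10 splits, too few for a share under 0.05. With a real count of 0, all 10 splits in each tissue gave as many probe sets; the highest other count was 4 in shoots and 22 in roots, each in a split with both arrays numbered 1 on the same side, which points to a structure of the samples by number. In shoots, where the numbers pair the samples mainly through number 1, 4 splits part all 3 numbers. The real one had 324 probe sets at an unadjusted p under 0.05 and the others between 239 and 282. These 4 splits are too few to tell the real one from chance. Splits with both arrays numbered 1 together had 1618 to 2818. For root against shoot of control plants, 1 of 10 splits gave as many as the real 9350, and the highest other gave 0. For the difference between tissues, all 100 drawn splits gave at least the real count of 0, the highest other giving 20. A count of 0 is reached by every split, so this says nothing about chance.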

How the results depend on the processing

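Counts of 0 for Cs in shoot and for the difference between tissues held in every alternative run, and the count of 9350 between control root and shoot moved between 7649 (stricter filter) and 10653 (array weights). For Cs in root the count was 1 with a pseudocount of 44, 5 without the 4 arrays numbered 1 (chosen after seeing the data), and from 0 to 7 when each array was left out, the 7 arising without Cs root replicate 1; the cause was not tested. Same-numbered root arrays deviated with correlations of 0.47, -0.02 and 0.40, so the data do not pair them at every number, though 244 probe sets differed by number in root. With root arrays alone and the replicate block, limma called 11 probe sets in root, 10 higher and 1 lower. In that fit 1263 had an unadjusted p under 0.05, above the even spread of 775.4. Among the 11 were AT3G55790 (33.4 ± 27.4 in control and 291 ± 189 in Cs roots), AT3G60420, UGT73D1 and CHI, each higher in Cs at all 3 numbers. CHI here is not a gene of the fixed flavonoid list. With the block over all 12 arrays the Cs counts and the difference stayed at 0. No call of the 5 fixed lists or the 19 added gene groups changed in any of the 4 contrasts. Root against shoot gave 10061 calls, 9322 of them shared with the 9350. This block takes the same number effect for both tissues, so it cannot tell whether these results hold under pairing within a tissue. Leaving out arrays moved the tissue count from 8365 to 9481, the number of shifted fixed lists in shoot and in root from 0 to 1, the photosynthesis median in root from -0.065 to 1.07 and the plastid-encoded median in root from -0.16 to 0.62. Both medians turned without Cs root replicate 2, where the plastid-encoded adjusted p was 0.0119, and both lost their call without control root replicate 2 (0.29 and 0.18) or 3 (0.50 and 0.17). A shoot list, flavonoid synthesis, passed as lower without Cs shoot replicate 1 or control shoot replicate 2 and turned to higher without control shoot replicate 1. Its genes were higher in the shoot arrays numbered 1, and with the block over all 12 arrays it stayed lower without passing (camera adjusted p = 0.084). With an estimated correlation 0 fixed lists passed in root, and the medians of 0.61 and 0.25 lost their call, as did those of the difference between tissues, 0.73 and 0.19. When each array was left out, the latter moved from 0.061 to 1.215 for photosynthesis and from -0.25 to 0.63 for the plastid-encoded genes, each lowest without Cs root replicate 2. The photosynthesis difference also lost its call without control root replicate 2 or 3 or control shoot replicate 1, and the plastid-encoded one without control root replicate 2 or 3, control shoot replicate 2 or 3, or Cs shoot replicate 1. In shoots 1 of the 2 Actin pairs alone gave a Cs difference of -0.42 and the other 0.03, against -0.08 for the mean of all pairs. Of 400 alternative values of the 80 named results none changed direction and 1, AT4G08380 in root, passed, but adjusted p-values near 1 leave little room to move. Fold changes moved by over 1.5 times in 30 of 80 with a pseudocount of 44, in 8 with 2.75, in 8 with array-median centring, in 7 with quantile normalization and in 0 with the block.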

Other observations

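The listed class III peroxidases, enzymes that cross-link or loosen cell walls, were the added gene group most tilted to the root. The list was chosen by locus and is not the whole family, so the tilt holds for its members only. Of 18 tested members 16 were higher in control roots and 0 lower, with a median log2 difference of 3.39 (camera adjusted p = 4.64e-05, and 0.45 with an estimated correlation). AT4G30170 and AT5G17820 were higher in root by 5.47 and 5.11. Cytosolic ribosomal protein genes were higher in root in 24 of 32 cases, by a median of 0.64 (adjusted p = 0.00301, and 0.67 with an estimated correlation), and of 68 plastid-encoded probe sets 67 were lower in root, by a median of -3.25. Of the SWEET sugar transporter genes 4 of 8 were lower in root, SWEET11 by -3.59, and SWEET16 was higher by 1.27. Of the 19 added gene groups, 0 shifted with Cs in shoots by camera, the smallest adjusted p being 0.505. In roots 2 did with the preset correlation, the plastid-encoded genes (median 0.25) and the ribosomal protein genes (median -0.09, adjusted p = 0.0248). Both lost the call with an estimated correlation (adjusted p = 0.823 for each), and the plastid-encoded genes turned to -0.16 without Cs root replicate 2 (adjusted p = 0.0119).

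Some transcripts were high in Cs root replicates 2 and 3 and not in replicate 1. AT1G26380, which encodes a berberine bridge enzyme-like oxidase, had signals of 16.5, 120 and 195 in the Cs roots numbered 1, 2 and 3 and of 14.3, 23.4 and 25.4 in the control roots. AT1G22890 had 12.7, 57.7 and 71.2 against a mean of 13.9 ± 2.89 in control roots, and AT5G42830 had 96.7, 338 and 360 against 56.1, 118 and 93.3. Their log2 fold changes over all arrays were 1.52, 1.05 and 1.32, and none passed (limma, adjusted p = 0.9997 for each). AT1G26380 and AT1G22890 passed without Cs root replicate 1, and AT1G26380 and AT5G42830 passed without the arrays numbered 1. These 3 genes were chosen after their values were seen.

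The median signal of the 108 root-enriched probe sets was 7.54, 16.3 and 31.2 in the control shoots numbered 1, 2 and 3, and 10.8, 25.3 and 48.5 in the Cs shoots. Chosen in Cs plants in place of control plants, 93 root-enriched probe sets had a median shoot log2 fold change of 0.30, with 74 above 0.

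In shoots 3234 probe sets differed between number 1 and the mean of numbers 2 and 3, of which 1416 were higher and 1818 lower in number 1. Among the named genes with the smallest p on each side, the largest differences were those of AT1G56300 (-4.07), AT4G30650 (-3.86) and CCL on the lower side. On the higher side it was that of AT5G15950 (2.76). All 3 tested flavonoid genes were higher in number 1, by a median of 1.53, as were 17 of 32 ribosomal protein genes and 8 of 13 expansin genes, while 6 of 10 autophagy genes were lower. Each of these groups had an adjusted camera p of 0.692 with an estimated correlation. The 25S ribosomal RNA probe set read 3062 in control root 1 and 935 in Cs root 1, and between 63.5 and 458 in the other 10 arrays.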
